A study of Desmodus rotundus and Carollia brevicauda with 4 samples.

How the data were processed

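RNA of the TG and DRG of each bat was measured by sequencing, 1 library per group, 4 samples in all. Per the labels' protocols, tissue was fixed in paraformaldehyde, RNA was taken up in Trizol, polyadenylated RNA was enriched, and Illumina libraries were made from double-stranded cDNA. The authors deposited whole-number counts of reads per bovine RefSeq protein, with a total of reads as a further line that was left out of all tests. The deposited alignments give, without a header, a percent of identical residues, positions on the read and the protein, an E-value and a bit score for each alignment. Their layout is that of a translated search of reads of up to 80 nt against proteins, with E-values up to 8e-06 and a bit score of at least 45.1. The search program, its version and the release of the bovine proteins are not given in the sources used here. Positions in the deposited alignments were used as other values, in residues and nt. The vampire TG sample had 2 files of counts, which were summed and treated as 1 sample. The 2 files differed little more than sampling noise allows (chi-square per degree of freedom 1.10 over 9479 degrees of freedom, against 4.15 for the first vampire TG file against vampire DRG). The lanes of non-vampire TG differed beyond sampling noise, at 1.66 per degree of freedom over 11143, so lanes of 1 sample were not always alike.

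The counting rule was found from the deposited alignments: each alignment that had the highest bit score of its read added 1 count, so a read tied between proteins was counted for each of them. Counts made again by this rule were checked against the deposited ones and differed for 0 proteins in every count file. Between 18.5% and 21.3% of the reads of a library were tied between proteins. The non-vampire TG counts covered 3677699 of 7316574 aligned reads, those at the start of each of its lanes. Of the 21719 accessions, 9882 began with NP_, 11824 with XP_ and 13 with YP_. The reference table of the vampire bat used here, of the assembly HLdesRot8A.1, holds 110126 accessions, and 0 of the bovine accessions matched it. Levels of TRPV1 and of other TRP channels, breaks of alignments at the TRPV1 splice site and the medians of 22 gene lists had been planned before the data were examined. They need gene names, and were not analysed here. The named-gene rule, which took genes with a symbol by the bounds of their interval, was for the same reason applied to accessions, limited to the 2 with the highest lower bound and the 2 with the lowest upper bound in vampire TG against DRG. XP_879643 and the YP_ class were chosen after their values were seen. RefSeq uses YP_ for proteins annotated on a genome record such as that of a mitochondrion, and the members were not identified further.

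Counts were scaled by the counted reads of the library (CPM). Ratios between libraries have 95% exact Clopper-Pearson intervals of the conditional binomial share, and levels have exact Poisson intervals. Polymerase chain reaction copies are not independent molecules, so intervals and floors cover counting error only; the floor is 3 counts, the limit of a 1-sided interval, and lies below the upper bound of the 2-sided Poisson interval of 0 counts. A protein with at least 20 reads over both libraries was tested, and was called different at a ratio of at least 4-fold with the whole interval beyond 2-fold. The ratio of TG/DRG ratios used a normal approximation with 0.5 reads added. No p-value across proteins was computed, since groups had 1 library. Random lists were matched on expression within 100 ranks on each side. Protein length was taken as the last residue reached by any alignment. Each calling step was tested on simulated data with 200 changed proteins. In vampire TG against DRG 61 of 100 changes of 8-fold were recovered and 4 unchanged proteins called. In the non-vampire bat 99 of 100 were recovered and 0 called. Between the TG of the species 99 were recovered, and between the DRG 67.

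Alternatives were median-of-ratios size factors (DESeq2 1.42.0), TMM factors (edgeR 4.0.16), totals without the 100 proteins with most reads, a minimum of 100 reads or none, a 2-fold threshold, thinning to 212500 reads per library, a bit score of at least 50, identical alignments counted once, and each vampire TG file alone. The alternatives added after the data were seen were each read counted once per protein, only reads with 1 top protein, all aligned non-vampire TG reads, groups of proteins joined where they shared at least 50% of reads, no YP_ proteins, ratios centred within 20 bins of protein length, and thinning followed by counting identical alignments of a sample once. Without thinning, identical alignments were counted once within each file, which limits deeper libraries more. DESeq2 and edgeR served for scaling factors only. Scripts used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.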

Results

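The series measured polyadenylated RNA in sensory ganglia of the common vampire bat, Desmodus rotundus, and of a bat without facial pits, Carollia brevicauda, here called the non-vampire bat. Trigeminal ganglia (TG) carry sensation from the face, and dorsal root ganglia (DRG) carry it from the trunk and limbs. Each of the 4 groups held 1 library, so no difference below has a replicate check, and every interval covers counting error only. The counts covered 3451652 reads in vampire TG, 212500 in vampire DRG, 3677699 in non-vampire TG and 2039739 in non-vampire DRG. Each read had been assigned to bovine proteins. In vampire TG 15930 proteins had at least 1 count, against 11976 in vampire DRG, 16228 in non-vampire TG and 15036 in non-vampire DRG. These numbers follow depth: at 212500 reads each they were 12308, 11976, 12413 and 11154, lowest in non-vampire DRG. Levels are given as counts scaled by the counted reads of the library (CPM). By a floor of 3 counts, a protein with 0 counts could still stand at up to 0.869 CPM in vampire TG, 14.1 in vampire DRG, 0.816 in non-vampire TG and 1.47 in non-vampire DRG. The files do not pair the bovine accessions with gene names, so TRPV1, the heat-gated channel in the title of the series, was not analysed here, and proteins are given by accession.

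The vampire ganglia were the most alike pair of libraries, at full depth and at equal numbers of reads. Their read names share a prefix that carries no run number, so whether they were sequenced in a common run is not known. Each non-vampire library had a run name of its own. Across 10060 proteins, which are not independent replicates, Spearman's rho was 0.841 between vampire TG and vampire DRG and 0.806 between non-vampire TG and non-vampire DRG. It was 0.793 between the DRG of both species and 0.761 between their TG. With all libraries thinned to 212500 reads, the correlation was 0.792 within the vampire and 0.744 between the DRG of both species, but 0.719 within the non-vampire bat. The protein with most counts in every library was XP_879643, at 117580 CPM in vampire TG, 105125 in vampire DRG, 67993 in non-vampire TG and 72865 in non-vampire DRG. Reads aligned to this protein were counted 8.24 times each on average. Counted once per read, it stood at 14220 CPM in vampire TG and 8779 in non-vampire DRG. The 13 proteins with YP_ accessions took 10.02% of reads in vampire TG (95% exact binomial interval 9.99 to 10.05), 7.88% in vampire DRG (7.768 to 7.997), 14.04% in non-vampire TG (14.00 to 14.07) and 17.93% in non-vampire DRG (17.87 to 17.98).

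Vampire TG against vampire DRG asks which transcripts set the ganglion that serves the infrared-sensing face apart from the ganglia of the trunk. Few proteins differed. Of 11325 proteins tested, 147 were at least 4-fold different with an interval beyond 2-fold, 76 higher in TG and 71 lower. The balance of directions moved with the minimum of reads, to 76 higher and 19 lower at 100 reads and to 76 higher and 162 lower with no minimum. It also moved with the alignments used, to 125 higher and 54 lower with identical alignments counted once (36 and 36 when thinned to equal reads first) and to 24 higher and 34 lower at a bit score of at least 50. Higher calls stayed at 76 at each minimum, because against the shallow vampire DRG library a protein with few reads could not be called higher. The split and the number of calls at full depth are therefore tied to the unequal depths. Thinned to equal reads, 37 were higher and 38 lower. The proteins named next were picked as extremes of this ratio by the bounds of their intervals, which are not adjusted for that choice. NP_776378 stood at 1526 CPM in vampire TG, from 5266 counts, and at 4.71 in vampire DRG, from 1 count, a ratio of 324 (95% interval 58.2 to 12808). With alignments of a bit score of at least 50 the ratio of NP_776378 was 36.1 (6.45 to 1426), and with identical alignments counted once it was 121 (21.7 to 4782), or 214 (38.0 to 8492) when thinned to equal reads first. NP_776490 stood at 1319 CPM in TG and 9.41 in DRG, from 2 counts, a ratio of 140 (38.8 to 1158), or 79.4 (14.2 to 3136) at a bit score of at least 50. In the other direction XP_001255272 stood at 1.16 CPM in TG and 744 in DRG, a ratio of 0.00156 (0.000419 to 0.00407). NP_776542 stood at 1.74 CPM in TG and 786 in DRG, a ratio of 0.00221 (0.00080 to 0.00492). XP_001255272 and NP_776542 are not separate measurements, because 67.7% of the vampire DRG reads of XP_001255272 were also counted for NP_776542. With only reads of 1 top protein, NP_776542 kept 0 reads in TG and 19 in DRG, a ratio of 0 (0 to 0.0132), and fell short of the minimum of 20 reads. With libraries thinned to equal reads, XP_001255272 had 0 counts in TG and a ratio of at most 0.0236. The YP_ class was higher in TG, with a summed ratio of 1.27 (1.25 to 1.29), and 9 of its 12 measured members lay above 1. Its median log2 ratio of 0.31 lay at percentile 100 of 10000 random lists matched on expression. The summed ratio was 1.28 (1.25 to 1.30) at equal reads, and 1.17 (1.13 to 1.20) at equal reads with identical alignments counted once, where the median lay at percentile 99.9. At full depth with identical alignments counted once, which lowers the counts of a deeper library more, it turned to 0.430 (0.419 to 0.442), with 0 of 12 members above 1. The class was chosen after its values were seen. Its members may move together, unlike those of the random lists, so the percentiles here and below only describe these libraries. The vampire DRG library limited this comparison: at its depth 61 of 100 simulated 8-fold changes and 84 of 100 simulated 16-fold changes were recovered. The median log2 ratio of the proteins tested was 0.01.

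**Figure D1:**
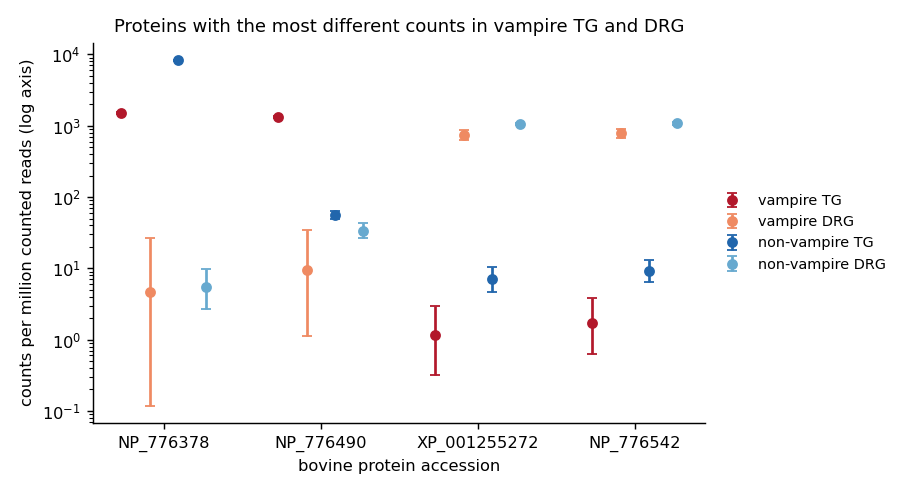
CPM, counts scaled by counted reads (log axis), of 4 proteins named by accession in the 4 libraries, 1 point per library, with 95% Poisson intervals as bars that cover counting error only. NP_776378 stands at 1526 in vampire TG and 8274 in non-vampire TG, whereas NP_776490 stands at 1319 in vampire TG and 56.3 in non-vampire TG.

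The same contrast in the non-vampire bat serves as background for the vampire ganglia. Here 1120 of 12205 proteins were different, 977 higher in TG and 143 lower. NP_776378 again differed, at 8274 CPM in TG and 5.39 in DRG, a ratio of 1534 (857 to 3074). That ratio was 37.8 (21.0 to 76.0) with identical alignments counted once, or 274 (48.7 to 10841) when thinned to equal reads first. NP_776490 did not pass the threshold, at 56.3 CPM in TG and 33.8 in DRG, a ratio of 1.66 (1.26 to 2.22). In 1 random draw thinned to equal reads that ratio was 0.50 (0.110 to 1.87), from 4 TG and 8 DRG counts, too few to show a change. XP_001255272 was lower in TG, with a ratio of 0.00664 (0.00433 to 0.00976), and so was NP_776542, with a ratio of 0.00859 (0.00593 to 0.0120). The YP_ class was lower in non-vampire TG, with a summed ratio of 0.783 (0.780 to 0.786), and 0 of its 12 measured members lay above 1. Its median lay at percentile 2.99 of random lists. The summed ratio was 0.785 (0.773 to 0.797) at equal reads, and 0.668 (0.649 to 0.688) at equal reads with identical alignments counted once, at percentile 1.85. At full depth with identical alignments counted once it was 0.502 (0.493 to 0.511). The proteins higher in TG were long: their median length was 827 residues, against 319 for the proteins lower in TG and 428 for all proteins tested. Above the upper quartile of length 577 were higher and 23 lower, and below the lower quartile 66 were higher and 50 lower. Across 7125 proteins Spearman's rho between the TG/DRG ratio and length was 0.485, against 0.175 across 6039 proteins in the vampire. The median log2 ratio was 0.39 under scaling to the read total, 0.00 under median-of-ratios scaling and 0.04 under TMM. The split of 977 higher and 143 lower, 87.2% higher, became 600 and 213 (73.8%) under median-of-ratios scaling and 632 and 205 (75.5%) under TMM. With ratios centred within bins of protein length, 511 were higher and 155 lower (76.7%). The YP_ class was not evaluated within these bins, and its random lists were not matched on length. An effect of length on its ratio was therefore not separated. With libraries thinned to equal reads, 115 were higher and 52 lower (68.9%), and the median log2 ratio of the proteins then tested was 0.02.

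**Figure D2:**
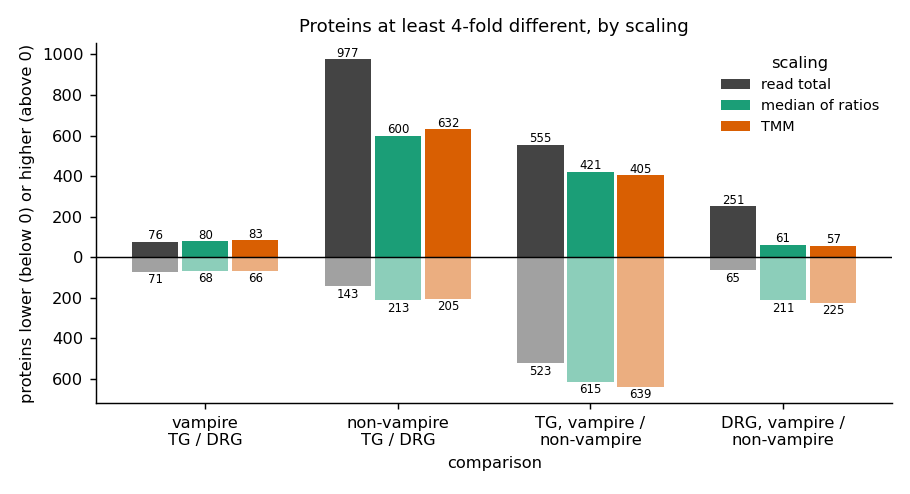
Number of proteins at least 4-fold higher (solid bars, above 0) or lower (pale bars, below 0) in each comparison of 2 libraries, under scaling to the read total, to median-of-ratios size factors or to TMM factors. Between the DRG of the species 251 proteins are higher and 65 lower under the read total, but 61 higher and 211 lower under median-of-ratios scaling.

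Between species the TG differed in 1078 of 13099 proteins, 555 higher in the vampire and 523 lower. NP_776490 was 23.4-fold higher in vampire TG (20.4 to 27.1), and 11.1-fold (9.56 to 12.9) with identical alignments counted once. It was 73.3-fold higher (28.3 to 271) when thinned, a value that rests on 1 draw with 4 counts in non-vampire TG. NP_776378 was lower there, at a ratio of 0.184 (0.179 to 0.190), but no longer passed the threshold at a bit score of at least 50, at 0.569 (0.521 to 0.621), or at equal reads with identical alignments counted once, at 0.650 (0.543 to 0.778). With identical alignments counted once at full depth its ratio was 1.60 (1.46 to 1.75). XP_001255272 was lower too, at 0.164 (0.0416 to 0.472), and so was NP_776542, at 0.188 (0.0645 to 0.453). These values rest on 4 and 6 counts in vampire TG, and neither passed the threshold when thinned. The YP_ class stood at a ratio of 0.714, with 1 of 12 members above 1 and its median at percentile 8.58, and at 0.714 at equal reads. At equal reads with identical alignments counted once it was 0.895 (0.867 to 0.923), with 4 of 12 members above 1, but without thinning it turned to 1.23 (1.21 to 1.25), with 6 of 12 above 1. The share of higher calls was 51.5% under scaling to the read total, 40.6% under median-of-ratios scaling and 38.8% under TMM. It was 40.4% with ratios centred within bins of protein length and 23.5% with identical alignments counted once, but 48.2% when thinned to equal reads first. Thinned to equal reads, 117 were higher and 64 lower. The median log2 ratio was 0.10 under the read total, -0.05 under median-of-ratios scaling and -0.09 under TMM. Species and sequencing run could not be separated, because no run name was shared by libraries of both bats. Species ratios in TG and in DRG also include any protein-specific difference in how well each bat aligns to bovine proteins.

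The DRG of the species differed in 316 of 8543 proteins, 251 higher in the vampire and 65 lower, and this direction depended on the scaling, the minimum of reads and the treatment of identical alignments. Under median-of-ratios scaling 61 were higher and 211 lower, and the share of higher calls moved from 79.4% to 22.4%, or to 20.2% under TMM. Without the 100 proteins with most reads in the total, 131 were higher and 103 lower, without the YP_ proteins 175 and 85, and within bins of protein length 137 and 88. Scaled to the read total, a minimum of 100 reads gave 31 higher and 58 lower (34.8%), and identical alignments counted once gave 39 and 155 (20.1%), or 45 and 46 when thinned to equal reads first. Thinning alone gave 87 higher and 42 lower (67.4%). With the shallow vampire DRG library, a protein with few reads could be called higher in the vampire but not lower. The split at full depth is therefore also tied to the unequal depths. The median log2 ratio was 0.40 under the read total, -0.18 under median-of-ratios scaling and -0.21 under TMM. XP_001255272 did not pass the threshold, at a ratio of 0.699 (0.591 to 0.821), and neither did NP_776542, at 0.730 (0.620 to 0.855). The YP_ class stood at a ratio of 0.440, with 0 of 12 members above 1, 2 members lower by the threshold and its median at percentile 0. The ratio was 0.293 under median-of-ratios scaling and 0.288 under TMM. It was 0.439 at equal reads, and 0.513 (0.497 to 0.529) at equal reads with identical alignments counted once, but without thinning the latter turned to 1.44 (1.40 to 1.47), with 6 of 12 above 1.

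The TG/DRG ratio itself was compared between the species. Of 13531 proteins, 616 differed at least 4-fold, 33 higher in the vampire and 583 lower. The median log2 ratio was -0.45, against 0.39 for TG against DRG in the non-vampire bat and 0.01 in the vampire. This contrast reuses the non-vampire counts, so its split is not separate from the 977 higher and 143 lower in non-vampire TG against DRG. The split and number of calls at full depth are also tied to the unequal depths. NP_776490 had a TG/DRG ratio 67.7-fold higher in the vampire than in the non-vampire bat (19.0 to 241). It was picked for its high TG/DRG ratio in the vampire, and the same vampire counts enter here, so the choice favours a large value. The value was 222 (40.9 to 1202) when thinned and 38.4 (7.35 to 200) at a bit score of at least 50, and passed the threshold in both. The thinned value rests on 1 draw with 4 counts in non-vampire TG and 8 in non-vampire DRG. NP_776378 had a ratio of 0.147 (0.0269 to 0.808), which did not pass the threshold. The ratio of NP_776378 turned to 2.23 (0.406 to 12.3) with identical alignments counted once, and was 0.783 (0.0809 to 7.58) when thinned to equal reads first. At a bit score of at least 50 it was 0.0135 (0.000548 to 0.331), which passed the threshold as lower in the vampire. That value rests on 1 count in vampire DRG and 0 in non-vampire DRG. The direction for NP_776378 thus depended on the alignments used and was not determined. The share of higher calls was 5.4% under the read total, 20.9% under median-of-ratios scaling and 20.2% under TMM. Thinned to equal reads, 29 proteins were higher and 72 lower (28.7%), or 33 and 53 with identical alignments then counted once. Within bins of protein length 46 were higher and 364 lower. On simulated counts this contrast called 19 unchanged proteins and recovered 60 of 100 changes of 8-fold.

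Part of the TG/DRG difference was common to the species. Among 10725 proteins tested in both, 18 were higher in TG in both bats, where independent lists would share 4.84, and 26 were lower in both, where independent lists would share 0.490. These comparisons have no library in common. Proteins that share reads, such as XP_001255272 and NP_776542, were counted separately in these overlaps, so part of the excess may be repeated measurement. A single protein was higher in vampire TG and lower in non-vampire TG, where independent lists would share 0.469, and 0 showed the reverse, where they would share 5.05. Across 5478 proteins with at least 100 reads in each species, Spearman's rho between the TG/DRG ratios was 0.367 and Pearson's r was 0.467. The species difference was likewise partly common to the ganglia: among 8484 proteins, 54 were higher in the vampire in both, against 5.62 for independent lists, and 23 were lower in both, against 1.72. These numbers moved with the scaling, to 20 higher and 53 lower under median-of-ratios scaling and to 19 and 60 under TMM. Across 3322 proteins rho between the species ratios in TG and DRG was 0.606. A protein-specific difference in how well each bat aligns to bovine proteins would appear in both ganglia. It was not separated from a difference in expression.

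**Figure D3:**
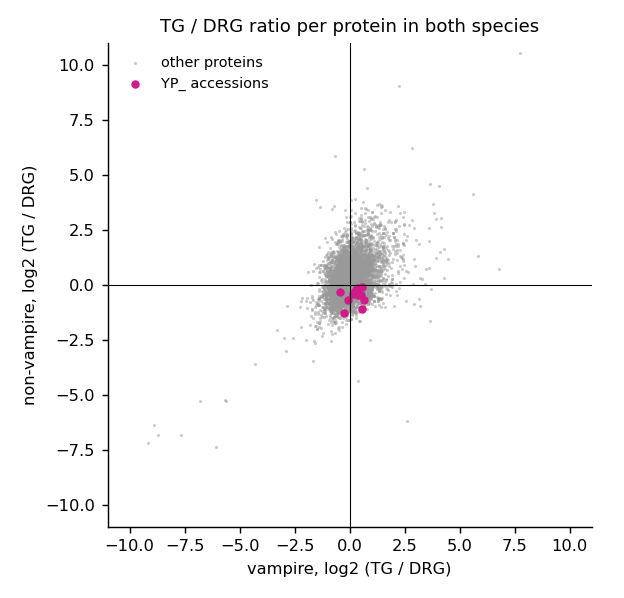
Log2 ratio of TG to DRG for 5478 proteins with at least 100 reads in each species, vampire on the x axis and non-vampire on the y axis, 1 point per protein, with 0.5 reads added to each count. Proteins with YP_ accessions are marked in pink and lie below 0 on the y axis; Spearman's rho is 0.367.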

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

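The tests of identical alignments at equal reads, repeated alignments, separate runs, 3' ends, length as the whole cause, divergence and lane errors were chosen after the result was seen.

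The YP_ class moved in opposite directions in the species, with a summed TG/DRG ratio of 1.27 in the vampire and 0.783 in the non-vampire bat; the difference was not tested beyond counting error. At equal reads the ratios were 1.28 and 0.785, and with identical alignments then counted once 1.17 and 0.668. At full depth with identical alignments counted once, which lowers deeper libraries more, both lay below 1, at 0.430 and 0.502. In the non-vampire bat the TG/DRG ratio rose with protein length (rho 0.485). The class was not evaluated within length bins, so length was not separated from a difference between the species. In 616 proteins the TG/DRG ratio differed at least 4-fold between the species by its own interval. That number is tied to the unequal depths and was 101 at equal reads. The 1 protein higher in vampire TG and lower in non-vampire TG is close to the 0.469 that independent lists would share. A further 3638875 aligned non-vampire TG reads lie outside the deposited counts. The alignments also hold 1389 accessions with no line in the counts, reached by 0.0475% of vampire DRG reads and 0.0659% of non-vampire TG reads.

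XP_879643 had the most counts in each of the 4 libraries. Its counts exceeded its reads 8.24 times, and nearly all of its neighbouring tied alignments lay 76 residues apart. Separate counting of tied alignments in a protein of repeated units is a candidate explanation of its rank, because it stood at rank 20 with each read counted once. No biological explanation was tested.

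In non-vampire TG against DRG far more proteins were higher than lower. Reads shared between similar proteins are argued against as the cause, since 88.0% of calls were higher with reads of 1 top protein, and depth accounts for part but not the whole of the larger number of calls than in the vampire, which was 7.62 times as large at full depth and 2.23 times at equal reads. At equal reads 68.9% of calls were higher. Repeated alignments then made up 25.4% of reads in non-vampire TG and 29.6% in non-vampire DRG, against 14.1% and 15.3% in vampire TG and DRG. With identical alignments then counted once, the non-vampire bat had 147 calls and the vampire 72. Loss of long transcripts from the DRG library is a candidate explanation for at least part of it (rho 0.485 between ratio and length). With ratios centred within bins of length 76.7% of calls stayed higher. Aligned bovine protein length stands only roughly for transcript length, so this does not decide whether length is the whole cause. Scaling (73.8% higher under median-of-ratios scaling) and RNA fragments read near their 3' ends stay open. Reads in long proteins lay nearer the C-terminus in DRG by 0.0238 of the protein (SD 0.0592). The same shift was -0.0147 (SD 0.0541) between the vampire ganglia, and 0.0532 (SD 0.0695) from vampire DRG to non-vampire DRG. The libraries shared 0 run names, so run and ganglion cannot be told apart, and a difference between the ganglia remains untested.

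Identity to the bovine proteins differed between libraries, from 90.4% in vampire DRG to 92.4% in non-vampire DRG. Divergence of the species from cow as the whole cause is excluded by a mean difference of 1.57 percentage points per protein between the vampire ganglia (SD 1.15, 1619 proteins). Read errors that differ between lanes are a candidate explanation, since the vampire TG files, which come from 1 sample, differed by 0.477 points (SD 1.11), with 5208 of 7297 proteins on the same side. Vampire minus non-vampire identity was -3.25 points in DRG (SD 1.63), with 1560 of 1624 proteins lower in the vampire. In TG it was -0.729 points (SD 1.52), with 6640 of 9168 proteins lower. Both differences were larger in size than that between the vampire TG files. A part that follows the species was not separated from the runs.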

How the results depend on the processing

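Alternatives of read assignment, all non-vampire TG reads, joined proteins, no YP_ proteins, length bins and thinning before identical alignments were counted once were chosen after the data were seen. Of the counts of proteins under alternatives, 118 lay within 1.5 times the reported count and 70 did not. No paired analysis was possible because each group had 1 library and the labels give no replicate numbers. Alternatives for TRPV1, TRP channels, gene lists and the splice site were not run, for want of gene names. The floor of vampire DRG was 14.1 CPM. NP_776378 had 0 non-vampire DRG counts at a bit score of 50, so no ratio directly against that library is given. Its ratio of TG/DRG ratios, for which reads were added to each count, was then 0.0135 (0.000548 to 0.331). That value passed the threshold as lower in the vampire, but rests on 0 non-vampire DRG counts and 1 vampire DRG count.

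In the order vampire TG against DRG, non-vampire TG against DRG, TG between species, DRG between species and TG/DRG ratio between species, a minimum of 100 reads gave 95, 523, 520, 89 and 399 proteins, a 2-fold threshold 1006, 4002, 4375, 2007 and 2663, thinning 75, 167, 181, 129 and 101, and thinning with identical alignments once 72, 147, 139, 91 and 86. With no minimum vampire TG against DRG had 238 and DRG between species 490. A bit score of 50 gave 58 and 172 for that pair. Identical alignments counted once gave 194 for DRG between species and 382 for the TG/DRG ratio, which had 369 under median-of-ratios scaling, 371 under TMM and 410 in length bins. Non-vampire TG against DRG had 666 in length bins. Proteins higher in TG in both bats numbered 11 under median-of-ratios scaling, 305 at 2-fold, 5 thinned, 8 at a bit score of 50, 32 with identical alignments once, 4 when thinned first and 9 in length bins. Proteins lower in both numbered 13 at 100 reads, 52 with no minimum, 102 at 2-fold and 17 thinned with identical alignments once. Proteins higher in the vampire in both ganglia numbered 20 under median-of-ratios scaling, 19 under TMM, 32 without the 100 top proteins, 11 at 100 reads, 102 with no minimum, 634 at 2-fold, 19 thinned, 23 at a bit score of 50, 30 in length bins, and 8 with identical alignments once, thinned or not. Those lower in both numbered 53, 60 and 36 under the same scalings, 209 at 2-fold, 7 thinned, 50 with identical alignments once and 11 when thinned first. The single protein higher in vampire TG and lower in non-vampire TG became 2 under median-of-ratios scaling, TMM and length bins, 5 at 2-fold, and 0 when thinned (with identical alignments once or not), at a bit score of 50 or with the second vampire TG file alone. The reverse became 31 at 2-fold and 1 when thinned, with identical alignments once or not. Beyond the threshold and depth, the cause was not tested.

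The share of higher calls with identical alignments counted once was 69.8% in vampire TG against DRG, 23.5% in TG between species and 20.1% in DRG between species. Reversed ratios were that of NP_776490 in non-vampire TG against DRG when thinned (0.50, or 0.472 with identical alignments once, from 4 TG and 8 DRG counts) and those of the YP_ class with identical alignments counted once: 0.430 in vampire TG against DRG, 1.23 in TG and 1.44 in DRG between species. The ratios of NP_776378 then turned too, to 1.60 in TG between species and 2.23 in the TG/DRG ratio. By construction, this caps covered proteins most in deeper libraries. It was applied within each vampire TG file, so an alignment could count once in each of the 2 files. The TG samples had similar numbers of reads, 3451652 and 3677699, so depth was not shown to cause the reversals between them. Thinned first, none of these YP_ and NP_776378 ratios reversed. NP_776542 had a ratio of 0 in vampire TG against DRG with reads of 1 top protein, below the minimum of reads.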

Other observations

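The test of coverage along proteins was chosen after the result was seen.

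Reads from transcripts less alike to the bovine protein may have been lost more often in vampire DRG, whose reads aligned with the lowest identity. Across 4686 proteins rho between the vampire TG/DRG ratio and identity was -0.219, with a median log2 ratio of 0.13 below the lower quartile of identity and -0.21 above the upper. The relation is weak and rests on 1 library of each ganglion.

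Alternative splicing that differs between ganglia could change where reads fall along a protein. Among 216 vampire proteins with 100 reads in each ganglion, 0 had cumulative read positions at least 0.3 apart, which allows up to 1.39% of proteins and does not decide the question. In the non-vampire bat 27 of 2174 proteins did, against 1 of 4372 between lanes of non-vampire TG. These lanes come from 1 sample, so they do not show how separate libraries of 1 ganglion would differ. Reads in long proteins also lay nearer the C-terminus in non-vampire DRG than in TG, by 0.0238 of the protein. Splicing was not separated from such differences between libraries. Between species the number was 113 of 2385 in TG and 24 of 217 in DRG. What sets the 27 proteins apart stays open.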
